A study of Homo sapiens with 5 samples.

How the data were processed

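Total RNA from 1 pool of vastus lateralis muscle biopsies labelled insulin resistant was measured on 5 Affymetrix array designs, Hu35K subA, subB, subC and subD and HuFL. All 5 samples form 1 group. They are the same pool on different designs, so only the control probe sets that all designs carry were measured 5 times, and replicate numbers were given in accession order as names. The values are intensity as deposited, 1 whole number per probe set. The software, background correction and scaling behind these values were not given in the sources used here. On each array 31.9% to 38.8% of the values are negative, so they were read as differences between matched and mismatched probes, an assumption that no source used here states. No further scaling or log transform was applied, and no log scale was used because of the negative values. Other pools or groups were not analysed here. All columns of values belonged to the 5 samples (0 unmatched).

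The 58 control probe sets per array were kept apart, which left 42553 probe sets. Gene symbols came from the platforms' annotation, which can be old. Looking up their gene identifiers in a table of current human genes (assembly GRCh38.p14, used for names only) changed 0 symbols. Of the probe sets, 29711 named 1 gene, 857 several and 11985 none, and only those naming 1 gene were used for genes. A list symbol no longer in use was followed to its current name. Y-linked genes and XIST were not named.

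The noise SD of an array was the median absolute value of its negative signals divided by 0.6745, and the floor was 3 noise SDs. A gene was above the floor if at least 1 of its probe sets was. Each probe set was ranked within its own array as a percentile, and a gene's percentile was the median over its probe sets. The share of probe sets above the floor was given with its 95% Clopper-Pearson interval, which covers counting only. The 5 arrays limit the precision of the control values, and gene signals have no replicate.

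Before the data were examined, 20 gene lists with 474 genes were fixed, of which 423 genes were measured. For each list, the members above the floor were counted, and its median percentile was placed among 10000 random lists in which each gene was replaced by a random gene with the same number of probe sets (5 or more as 1 class). Matching on signal was not possible because signal was the quantity described. This place describes these arrays and is not a p-value. The rule for named genes was also fixed: per list, up to 4 members with the highest and up to 2 with the lowest percentile of the gene's highest probe set; on each array, the 5 highest signals of probe sets naming 1 gene; and the GAPDH and actin controls. Where more members of a list were listed at 0, ties were broken by symbol. Genes outside the rule are said to have been chosen after their values were seen.

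For control probe sets of either strand above the floor on all 5 arrays, the mean, SD and coefficient of variation were computed, with 3' over 5' ratios for GAPDH and actin. For genes on both HuFL and Hu35K, the mean percentile per side was compared by Spearman and Pearson correlation with 1000 random pairings and 1000 bootstraps. For genes chosen as above the floor on at least 1 side, the same choice was applied to each random pairing, a comparison added after seeing the data. The alternatives fixed in advance were floors of 2 and 5 noise SDs, a floor at the highest Bacillus control signal, only probe sets without a letter code (letter codes mark probe sets that can match several transcripts, or that were built under relaxed rules), the highest probe set per gene, scaling by the 2% trimmed mean or by the median signal above the floor, all controls with a mean above 0, only genes above the floor on at least 1 side, and leaving out each array. Leaving out the exact zeros of HuFL (also for families of genes read from their symbols), matching random genes on having a HuFL probe set, and keeping only antisense control probe sets were added after seeing the data.

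The computation was tested on simulated data. Over 5 simulated arrays with 42553 probe sets, the noise SD was recovered at 0.976 to 1.01 times its true value. The simulated noise was normally distributed, as the noise SD assumes, so this checks the computation and not the choice of floor. Among 14746 genes, 4.5% of unchanged lists of 20 genes fell outside the middle 95%, and lists raised by 10, 20 and 30 percentile points were recovered in 26%, 66% and 98% of 50 lists each. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.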

Results

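The data came from 1 pool of total RNA (pool 2) of human muscle labelled insulin resistant, taken by biopsy from vastus lateralis, a large muscle of the thigh. The pool was measured on 5 Affymetrix oligonucleotide array designs, the 4 arrays of the Hu35K set (subA, subB, subC and subD) and HuFL, which carry different probe sets for the most part, with 2856 genes measured on both HuFL and the Hu35K set. The number of people in the pool was not given in the sources used here, and no insulin-sensitive or control sample was analysed here. The arrays therefore describe which transcripts gave signal in this pool and how far the arrays agreed, and say nothing on what differs in insulin resistance. There were no replicates, so no test between conditions was made and gene signals carry no error. Signals are given as deposited and as multiples of the noise floor of the array that carried the probe set. Probes differ in affinity, so these values order signals within an array, not the abundance of transcripts. Genes named together can come from different arrays, whose signals as deposited differ in scale. Members of a list are ranked by the percentile of their highest probe set within its array.

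Genes of the contractile apparatus gave some of the highest signals on the arrays. In the fast-fibre list, 12 of 14 measured genes had a probe set above the floor, and in the slow-fibre list 8 of 9 did. ATP2A1, the calcium pump of fast fibres, had the highest signal of any gene on HuFL, at 37978 or 44.7 times the floor. MYOZ1, a Z-disc protein, reached 8153 on Hu35K subB (42.6 times the floor), MYBPC2, the fast myosin-binding protein C, 31979 on HuFL (37.6 times) and MYL1, a fast myosin light chain, 19534 on Hu35K subA (34.9 times). Among slow-fibre genes, TNNT1, slow troponin T, had a signal of 23079 (27.2 times the floor), TNNC1, troponin C of slow and cardiac muscle, 20799 (24.5 times) and MYL3, a slow light chain, 20295 (23.9 times), all on HuFL. ATP2A2, the calcium pump of slow fibres, reached 9038 on Hu35K subD (29.5 times), with 1 of its 4 probe sets above the floor. CASQ2, a calcium-binding protein of the sarcoplasmic reticulum, was 1.56 times the floor. In the fast-fibre list, PVALB (234 on HuFL) and TPM1 (85 at its highest-ranked probe set, on Hu35K subD) were not above the floor. Whether human fast fibres express every gene of that list was not tested. MYL2 of the slow-fibre list was listed at 0. The myosin heavy chains, chosen after their values were seen, were bright for both fibre types. On HuFL, MYH7 of slow fibres was at 19938 (23.5 times the floor) and MYH2 at 28637 (33.7 times). On Hu35K subD, MYH1 was at 9665 (31.5 times). Without HuFL, 7 of 8 fast-fibre and 5 of 5 slow-fibre genes still measured were above the floor. The myosin heavy chains are close in sequence, and cross-hybridisation among them was not tested.

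Sarcomere genes shared by the fibre types and genes of excitation-contraction coupling were bright as well. Of 19 genes in the shared sarcomere and Z-disc list, 14 were above the floor, among them the oxygen store MB (30365, 35.7 times the floor), the M-band protein MYOM1 (10431, 34.0 times), the Z-disc protein TCAP (9416, 30.7 times) and the thin-filament protein NEB (18658, 22.0 times). Whether every listed gene, such as MYL6, belongs to the sarcomere of human fibres was not tested. MYBPC1 and MYL6 were listed at 0, as were ACTA1 and CKM, chosen after their values were seen. With the zeros of HuFL left out, 14 of 15 members were above the floor. In the excitation-contraction coupling list, 10 of 15 genes were above the floor. SLN, a small inhibitor of the calcium pump, reached 26316 (31.0 times the floor), RYR1, the calcium release channel, 4544 (17.6 times), TRDN, which anchors at the calcium release channel, 6831 (12.2 times) and PLN, another pump inhibitor, 7737 (9.11 times). The calcium channel subunit CACNB1 (143) and the acetylcholine receptor subunit CHRND (130) were not above the floor. Without HuFL, 7 of 7 sarcomere and 4 of 7 coupling genes still measured were above it.

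Genes of oxidative phosphorylation were above the floor almost throughout. Complex I had 24 of 29 measured genes above the floor and complexes II to V 34 of 39. The highest-ranked complex I members were NDUFA1 (10018, 17.9 times the floor), NDUFA8 (1586, 8.29 times), NDUFB9 (6536, 11.7 times) and NDUFC1 (6114, 10.9 times), while NDUFB5 (200) and NDUFB2 (-46) were not above it. Among complexes II to V, the ATP synthase genes ATP5ME, ATP5F1D and ATP5MC3 reached 11578, 6709 and 1991, or 20.7, 26.0 and 10.4 times their floors. ATP5F1D was above the floor on 2 of 3 probe sets and ATP5MC3 on 2 of 5. COX7A1, the muscle form of a cytochrome c oxidase subunit, reached 24250 (28.5 times). ATP5PB was not above the floor, with 1 of its 2 probe sets listed at 0, and the adenine nucleotide carrier SLC25A4 was listed at 0. Complexes II to V had 16 of 21 genes above the floor without HuFL, and complex I 13 of 20 without Hu35K subA.

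In the lists of fuel use, between 12 of 20 and 16 of 23 genes were above the floor. Of 23 glycolysis and glycogen genes, 16 were above the floor. GAPDH reached 18092 on Hu35K subA (32.3 times the floor), ALDOA, muscle aldolase, 18228 (21.5 times), PGAM2, muscle phosphoglycerate mutase, 6739 (22.0 times) and PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1, 2781 (14.5 times). HK2, the hexokinase of insulin-sensitive tissues, was not above the floor on any of 3 probe sets, with 35 at its highest-ranked probe set. The phosphorylase kinase subunit PHKA1 was not above it either, with 1 of its 2 probe sets listed at 0. Of 21 genes of fatty acid uptake and oxidation, 13 were above the floor, led by ECI1 (3649, 6.51 times), ETFB (798, 4.17 times), ACADVL (7427, 8.74 times) and HADHA (2180, 7.10 times). Lipoprotein lipase, LPL, had a signal of 70 and was not above the floor, and HADH was listed at 0. Of 20 genes of the citric acid (TCA) cycle and pyruvate dehydrogenase, 12 were above the floor, with the malate dehydrogenases MDH2 (6527, 21.3 times) and MDH1 (5008, 5.90 times) and the succinyl-CoA ligase genes SUCLG2 (1188, 3.87 times) and SUCLG1 (1628, 2.90 times) highest-ranked. DLAT and IDH2 were listed at 0. Chosen after their values were seen, the fatty acid transporter CD36 was at 6083 (7.16 times the floor), UCP3 at 818 (2.67 times) and PDK4, a kinase that switches off pyruvate dehydrogenase, at 747 (1.33 times). CD36, UCP3 and PDK4 were each above the floor on 1 of 3 probe sets. Without HuFL, 10 of 15 glycolysis and 6 of 11 fatty acid genes were above the floor, and without Hu35K subA 6 of 20 TCA genes.

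At the floor of 3 noise SDs, genes of insulin signalling and glucose transport were above the floor in fewer than 50% of cases. This share depended on the floor. Of 31 measured genes, 13 (41.9%) were above the floor, against a mean of 34.2% in random lists, and 82.3% of random lists had a lower share. The highest-ranked were RAC1, a small GTPase (2731, 8.90 times the floor), PTPN1, a phosphatase of the insulin receptor (469, 2.45 times), AKT2 (763, 2.96 times) and FLOT1 (1998, 3.57 times). RAC1 was above the floor on 2 of 2 probe sets, PTPN1 and AKT2 on 1 of 4 each and FLOT1 on 1 of 3. PIK3R1 (-3) and PRKAB1 (-178) were not above the floor on any probe set. Further genes of the pathway were chosen after their values were seen: the glucose transporter SLC2A4 was 1.43 times the floor (1214, 2 of 3 probe sets above), AKT1 1.37 times (353, 4 of 7 above), TBC1D4 1.79 times (1005) and IRS1 1.23 times (688, 1 of 6 above). The insulin receptor INSR was not above the floor on any of 7 probe sets, the highest-ranked at 192 or 0.744 times the floor, and IRS2 (141) was not above it either. The list's median percentile of 64.1 was above that of 99.0% of random lists. This place fell to 91.4% when the zeros of HuFL were left out, to 93.6% with only probe sets free of a letter code, to 85.6% with each gene's highest probe set and to 96.0% without HuFL.

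Of 19 regulators of the PGC-1 and nuclear receptor group, 4 were above the floor, or 4 of 16 with the HuFL zeros left out. The share of 21.1% stood beside a mean of 32.2% in random lists, and 14.4% of random lists had a lower share. The count depended on the floor, with 7 of 19 above at 2 noise SDs and 10 of 19 with the highest Bacillus control as floor. The 4 were the myocyte enhancer factors MEF2D (1523, 7.96 times the floor) and MEF2C (4810, 15.7 times), the retinoid receptor RXRA (1065, 4.13 times) and PPARGC1A, the coactivator PGC-1 alpha (1361, 4.43 times, 1 of 3 probe sets above). The 1 PPARGC1A probe set above the floor, on Hu35K subD, has a letter code. With only probe sets free of a letter code, 3 of 18 genes were above the floor without PPARGC1A, and without subD 3 of 19. NR1H3 (-442) and ESRRA (-513) lay below 0. NRF1 reached 0.983 times the floor at its highest-ranked probe set (0 of 6 above) and TFAM 0.133 times (0 of 5 above), both chosen after their values were seen. The list's median percentile of 40.2 was the percentile of a value of 0 on HuFL. Its place among random lists was 5.88%, and 17.0% when these zeros were left out. Across the runs that left out 1 array each, that place ranged from 5.83% to 78.95%, the highest without HuFL.

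Of 44 cytosolic ribosomal protein genes, 40 were above the floor, with RPS27 (21926, 39.1 times the floor), RPS20 (12889, 42.0 times), RPS15 (11682, 45.3 times) and RPL41 (10448, 34.0 times) highest-ranked, while RPL28 (-215) and RPL5 (-175) lay below 0. RPS27 and RPL41 were above the floor on 1 of 2 probe sets each, and RPS20 and RPS15 on 1 of 3 each. For RPS27, RPS15 and RPL41, 1 other probe set each was listed at 0. Of 22 heat shock and redox genes, 14 were above the floor. The small heat shock protein HSPB1 had the highest signal on Hu35K subD outside the control probe sets (13781, 44.9 times). It was followed in the list by the chaperone HSPA8 (8549, 27.9 times, 1 of 2 probe sets above), the small heat shock protein CRYAB (15837, 18.6 times) and the ferritin light chain FTL (4131, 13.5 times). HSP90AA1 was listed at 0 and the peroxiredoxin PRDX2 had a signal of -143. Without HuFL, 16 of 27 ribosomal and 8 of 8 heat shock and redox genes were above the floor.

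Marker lists covered other cell types that a muscle biopsy can hold. Whether muscle fibres also express some of the listed genes, such as GPD1L, was not tested. In the extracellular matrix and fibroblast list, 4 of 23 genes were above the floor. These were SPARC (1139, 3.71 times the floor), COL1A2 (688, 2.24 times), DCN (325, 1.06 times) and COL6A2. For COL6A2, 1 of 3 probe sets was above while the highest-ranked, at 780, was 0.918 times its floor. SPARC was above the floor on 2 of 4 probe sets, COL1A2 on 1 of 6 and DCN on 1 of 2. LAMB1 (-28) and LAMA2 (-46) lay below 0. In the adipocyte list, 4 of 11 genes were above the floor, CFD (1532, 2.73 times), GPD1L (1385, 1.63 times), ADIPOQ (1189, 1.40 times) and PLIN1 (533, 1.74 times), whereas LIPE (-19) and LEP (-91) lay below 0. The endothelium and smooth muscle list is called endothelium for short below, though it also holds smooth muscle genes. In it, 3 of 15 genes were above the floor, RGS5 (2642, 4.71 times), VWF (1362, 4.44 times) and MYH11 (977, 3.18 times). RGS5 was above it on 1 of 6 probe sets, VWF on 1 of 2 and MYH11 on 1 of 3. FLT1 (613) was not above the floor, and KDR (-412) and CLDN5 (-516) lay below 0. In the blood and immune list, 7 of 18 were above, led by the immunoglobulin gene IGHM (2193, 7.15 times), HLA-DRA (3539, 4.17 times), CD3E (2032, 2.39 times) and ALAS2 (1238, 2.21 times), while NKG7 (-166) and CD14 (-1176) lay below 0. In the nerve and Schwann cell list, 2 of 7 were above, MBP (309, 1.62 times, 2 of 9 probe sets above) and SOX10 (371, 1.44 times). NCAM1 (427) and NEFH (189) were not above the floor, and S100B (-56) and NEFM (-191) lay below 0. Left-out arrays moved these small counts, to 2 of 7 adipocyte genes without HuFL, 1 of 15 endothelium and 1 of 23 matrix genes without Hu35K subD, and 1 of 6 nerve genes without subC.

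Lists of liver and brain genes, tissues that were not sampled, served as a comparison for these counts. Whether cells of the biopsy, such as those of nerve, also express some of these genes was not tested. Of 23 liver genes, 4 were above the floor, F2 (687, 3.59 times), APOC3 (1109, 3.61 times), TTR (1037, 3.38 times) and TF (953, 1.70 times), and APOB (-4) and HPX (-372) lay below 0. F2 was above the floor on 1 of 3 probe sets, APOC3 on 2 of 2 and TTR and TF on 1 of 4 each. Of 21 brain genes, 7 were above, the highest-ranked being MAG (1169, 4.53 times), GFAP (1380, 1.62 times), GRIA1 (226, 1.18 times) and NRGN (221, 1.16 times), and ENO2 (-55) and GAD1 (-309) lay below 0. MAG was above the floor on 1 of 3 probe sets, GRIA1 on 1 of 5 and GFAP and NRGN on 1 of 2 each. The shares above the floor were 17.4% for liver and 33.3% for brain, beside 17.4% for matrix, 20% for endothelium and smooth muscle, 28.6% for nerve, 36.4% for adipocyte and 38.9% for blood. Random lists had mean shares of 29.1%, 25.4%, 27.7%, 27.4%, 32.0%, 23.3% and 27.6% in the same order. The share of random lists that lay lower ran from 10.7% for liver to 85.5% for blood. The order of the 7 list shares depended on the floor: at 5 noise SDs, 2 of 21 brain, 4 of 23 liver, 2 of 23 matrix, 3 of 15 endothelium, 0 of 7 nerve, 2 of 11 adipocyte and 6 of 18 blood genes were above it. With only probe sets free of a letter code, 2 of 16 brain and 4 of 15 blood genes were above it.

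Set against 10000 random lists of the same size, 12 of the 20 lists had a median percentile above the middle 95% and none was below it. About 1 of 20 lists of random genes would fall outside. The lists were composed by function, cell type or tissue, several of them of muscle genes, so this count describes them and is no test. Fast-fibre (99.9), slow-fibre (96.0), ribosomal (95.8), complexes II to V (95.7), complex I (95.5), glycolysis and glycogen (95.2), shared sarcomere (93.8), excitation-contraction coupling (91.1), heat shock and redox (88.0) and fatty acid (85.7) lists had median percentiles above 100% of the random lists. The TCA list (73.7) was above 99.6% of them, but above 86.8% without Hu35K subA. The adipocyte list (72.8) was above 96.4%, and above 98.1% without Hu35K subD. The brain (52.3), matrix (49.2), liver (47.6), endothelium (45.5), nerve (40.2) and blood (40.2) lists lay within the range of random lists, at places of 57.4%, 39.1%, 28.7%, 27.1%, 15.3% and 8.08%. None of these left the middle 95% when 1 array was left out, but the places moved widely. Without HuFL they were 92.5% for endothelium, 52.8% for blood, 48.7% for nerve and 4.48% for liver. Without Hu35K subA the blood place was 16.3%, without subB the liver place was 60.5%, and without subC those of brain and endothelium were 27.0% and 10.1%. Without subD they were 27.6% for blood, 16.2% for matrix and 11.9% for endothelium. The blood place was 44.9% and the matrix place 65.6% with the HuFL zeros left out. The endothelium place was 1.45% with each gene's highest probe set, and the nerve place was 2.23% with the HuFL zeros left out.

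**Figure D1:**
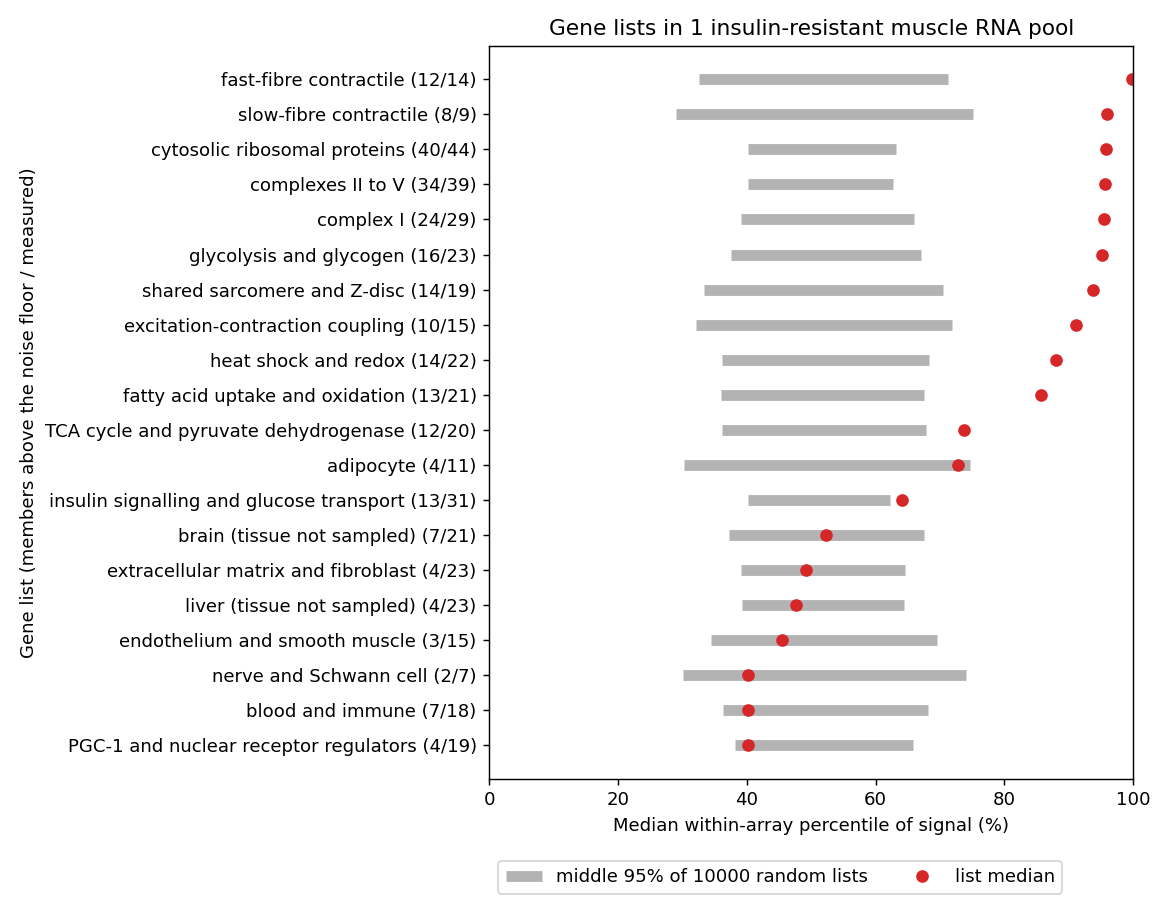
Median within-array percentile of signal (horizontal axis, in percent) of each of 20 gene lists in the insulin-resistant pool (vertical axis, with members above the noise floor over members measured). Points are list medians and grey bars hold the middle 95% of 10000 random lists; the fast-fibre list lies highest at 99.9, and 12 lists lie to the right of their bar.

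Taken over all arrays and with control probe sets left out, the 5 brightest probe sets naming 1 gene per array included genes of contraction, calcium handling, the ribosome and small heat shock proteins. On Hu35K subA they were RPS27, MYL1, NRDC (18698), GAPDH and NDRG2 (16206). On Hu35K subB they were MYOZ1, the small heat shock protein HSPB7 (5439), CCDC69 (3851), CHCHD10 (3686), a mitochondrial protein, and UBXN6 (3652). On Hu35K subC, CMYA5, a large muscle protein, took both top places (15352 and 12039), followed by RPS15, CASQ1 (11645), the calcium-binding protein of the sarcoplasmic reticulum in fast fibres, and GAPDH (9427). On Hu35K subD they were HSPB1, RPS20, HSPB6 (11445), TXNIP (11184), which restrains glucose uptake, and TNNI2 (10875), fast troponin I. On HuFL they were ATP2A1, MYBPC2, MB, the ubiquitin gene UBB (30082) and TNNC2 (28918), fast troponin C.

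Between 9.64% and 17.2% of probe sets were above the floor on an array. The counts were 1451 of 8876 on Hu35K subA (16.3%, 95% Clopper-Pearson interval 15.6 to 17.1), 855 of 8866 on subB (9.64%, 9.04 to 10.3), 1052 of 8870 on subC (11.9%, 11.2 to 12.6), 1525 of 8870 on subD (17.2%, 16.4 to 18.0) and 815 of 7071 on HuFL (11.5%, 10.8 to 12.3). These intervals cover the counting of probe sets only. Some signals lay as far below 0 as the floor lies above it. A signal of -1.12 times the floor had a percentile of 2.70 on subB, and -1.26 times one of 2.94 on subC. On subD, -1.14 times the floor had a percentile of 4.13, and on HuFL -1.12 times one of 3.34. A percentile is about the share of the array's signals at or below that value. These shares of 2.70%, 2.94%, 4.13% and 3.34% stand beside 9.64%, 11.9%, 17.2% and 11.5% above the floor on the same arrays. If noise spreads alike on both sides of 0, a part of the signals above the floor that is not small can be noise. This limit holds for every count of genes above the floor. In all, 3670 of 14746 genes (24.9%) had a probe set above the floor. The floors were 560.4, 191, 258, 307 and 849.5 in the same order, and 31.9% to 38.8% of signals were negative. HuFL also held 1047 probe sets at exactly 0, or 14.8%, against 15 to 72 probe sets on the Hu35K arrays, and 13.5% of its probe sets were above the floor with these zeros left out.

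**Figure D2:**
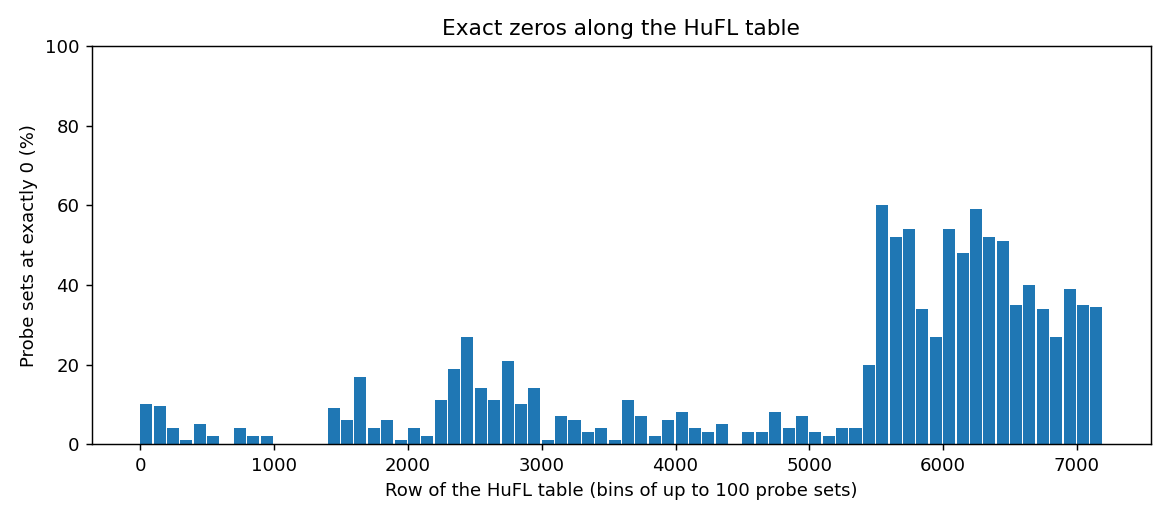
Percent of HuFL probe sets at exactly 0 (vertical axis) along the rows of the HuFL table (horizontal axis), in bins of up to 100 probe sets. Bars start at 0; probe sets named by accessions starting with X, Y or Z held 725 of the 1047 zeros.

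Control transcripts were measured on all 5 arrays, which carry the same 58 control probe sets. The GAPDH control had mean signals of 16050 ± 7648 at its 3' end, 14698 ± 7181 in the middle and 20868 ± 10000 at its 5' end (SD, n = 5 arrays). The actin control had 2480 ± 1606 at the 3' end, 4441 ± 2093 in the middle and 8242 ± 4342 at the 5' end. For the 13 control probe sets above the floor on all 5 arrays, 1 of them of the sense strand, the coefficient of variation was 40.4% to 64.8%, with a median of 47.9%. Their geometric mean was lowest on Hu35K subB. It was 1.61 times this lowest value on subC, 2.30 times on subD, 2.98 times on HuFL and 3.29 times on subA. Signals as deposited on different arrays therefore give no order between genes. The median coefficient of variation was 36.4% without subB. Within arrays, the 3' over 5' ratio was 0.771 ± 0.0707 for GAPDH and 0.342 ± 0.189 for actin (SD, n = 5), and the actin ratio was 0.120 on HuFL and 0.164 on subC against 0.423, 0.548 and 0.457 on subA, subB and subD. None of the 75 signals of Bacillus control probe sets was above its floor. The lowest Bacillus signals, however, were -571 on subA, -211 on subB, -297 on subC and -426 on subD. Each of these lay further below 0 than the array's floor lay above it (560.4, 191, 258 and 307). On HuFL the lowest was -579, against a floor of 849.5.

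**Figure D3:**
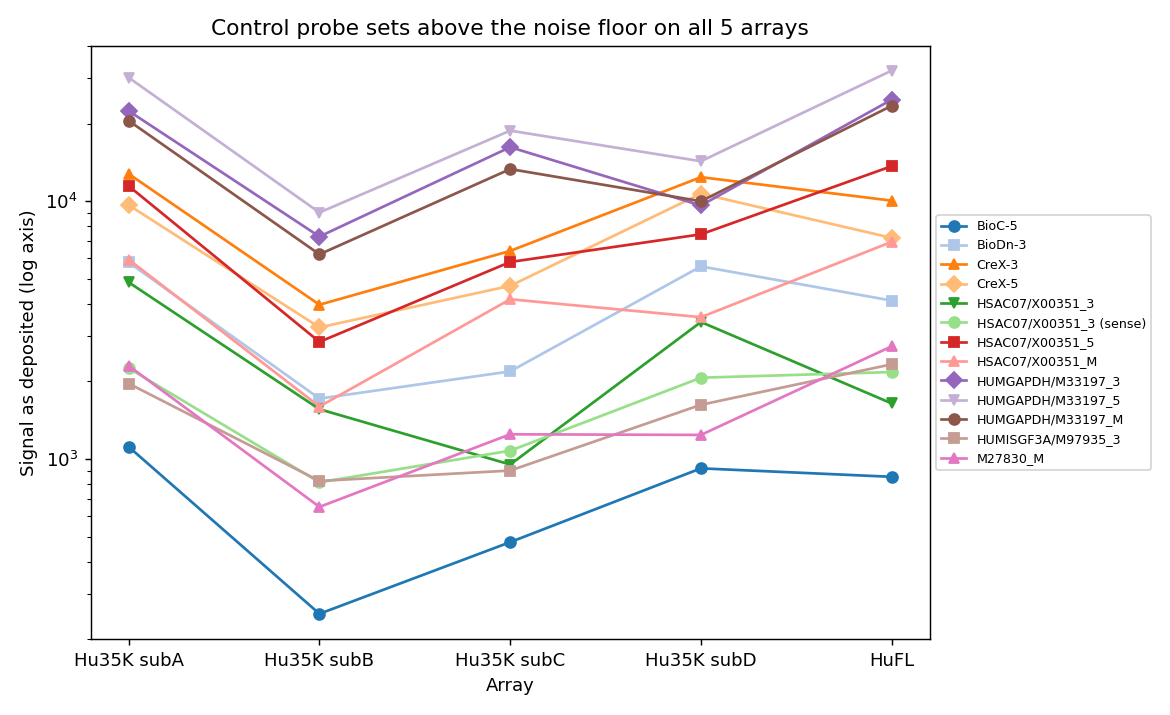
Signal as deposited (vertical log axis) of the 13 control probe sets, 1 of them of the sense strand, above the noise floor on all 5 arrays (horizontal axis). Each line joins the signals of the same probe set and stands for no order of the arrays; most lines are lowest on Hu35K subB, and the 3' actin control is lowest on Hu35K subC, at 952.

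Genes measured on both HuFL and the Hu35K set ranked only weakly alike. Over 2856 such genes, the Spearman correlation of within-array percentiles across genes was 0.141 (bootstrap 95% interval 0.104 to 0.184) and Pearson's was 0.145, against -0.0619 to 0.0634 in 1000 random pairings. Genes are not independent replicates, so no p-value is given. Of the 301 genes above the floor on HuFL, 153 (50.8%, 45.0 to 56.6, Clopper-Pearson) were also above it on Hu35K, against 565 of the 2555 genes not above it on HuFL (22.1%, 20.5 to 23.8). The correlation was 0.0672 over 1806 genes with probe sets free of a letter code. Among the 866 genes above the floor on at least 1 side it was -0.0484, but this selection alone lowers it, and 1000 random pairings under the same selection gave a mean of -0.343 (-0.421 to -0.265).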

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

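The tests of explanations below were chosen after the results had been seen. Of 20 quantities compared across the 5 arrays, 2 had an array far from the others. Chance alone marks about 1 in 20.

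HuFL held 14.8% of its probe sets at exactly 0, far above the Hu35K arrays (gap over range 0.956, critical value 0.71). Values of 1 and -1 were held by only 20 and 18 probe sets, and the zeros clustered among accessions starting with X, Y or Z (725 of 1661 or 43.6%, against 322 of 5410 or 5.95% elsewhere). Low signals rounded to 0 would put 8.92 zeros among the 142 HuFL probe sets of 7 bright lists (contractile, respiratory chain, glycolytic and ribosomal genes), whereas 22 were there (Poisson interval 13.8 to 33.3), which argues against that explanation. Values left out and written as 0, whatever their signal, would give 29.95 ± 4.39 (SD), so this remains a candidate explanation. No biological explanation was tested.

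The lowest signal on HuFL was -48329, far below the lowest on the other arrays (gap over range 0.878). These signals are as deposited, with no adjustment for the scale of each array. A probe set for the sense strand of the actin control at its 3' end had a mean signal of 1676 ± 677 (SD, n = 5) and was above the floor on all 5 arrays, the only 1 of 15 sense-strand control probe sets to be so.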

How the results depend on the processing

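Leaving out the zeros of HuFL (for lists and families), matching random genes on HuFL and keeping only antisense controls were chosen after the data were seen. Of 245 recomputed counts, coefficients of variation and correlations, 48 moved by over 1.5 times (counts), over 1 SD of the coefficients or out of the bootstrap interval of the correlation. Of 187 recomputed places among random lists, 179 stayed on the same side of the limits of the middle 95%, however far they moved within or beyond them, 5 fell inside these limits, 3 went outside and 0 changed from 1 end to the other. The place of the PGC-1 list, 5.88%, became 78.95% without HuFL and still counts among the 179. Each of 10 lists (both fibre types, sarcomere, excitation-contraction coupling, both respiratory chain lists, ribosomal, heat shock, glycolysis and fatty acid) stayed above at least 99.95% of random lists in every run without 1 array. Signal over background limits the counts: genes within a few noise SDs cannot be called with confidence, and a count can only fall when an array is left out. The cause of other shifts was not tested.

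With a floor of 2 noise SDs, probe sets above it numbered 1372 on subB and 1625 on subC, and the PGC-1 list had 7 genes above. With 5 noise SDs, 783 probe sets were above on subA, 409 on subB, 557 on subC, 924 on subD and 472 on HuFL, and 2 adipocyte, 2 brain, 2 matrix, 5 insulin signalling and 0 nerve genes were above. With the highest Bacillus signal as floor, which rests on 15 probe sets per array, 1427 were above on subB, 3229 on subC and 1774 on HuFL, with 10 PGC-1, 6 endothelium, 9 matrix and 7 liver genes. With only probe sets free of a letter code, 918 were above on subD, with 4 blood, 2 brain, 2 matrix, 10 glycolysis, 8 insulin signalling and 5 slow-fibre genes (of 7 measured), and the insulin signalling list's place was 93.6%. That place was 91.4% with HuFL zeros left out and 85.6% with each gene's highest probe set, where the endothelium place was 1.45%. The nerve place was 2.23% with HuFL zeros left out.

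The median coefficient of variation of controls was 37.2% after trimmed-mean scaling, 31.1% after scaling by the median above the floor and 64.8% over all controls with a mean above 0. The correlation of same-gene percentiles was 0.0672 with probe sets free of a letter code. It was -0.0484 among genes above the floor on at least 1 side, a selection that by construction lowers it (mean -0.343 in random pairings), so this value does not show weaker agreement.

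Without each array in turn, the coefficient of variation ranged from 36.4% to 53.4%, the lowest without subB. Without HuFL, the genes above the floor fell to the lowest of these ranges, with the number still measured in brackets: 16 (21) to 34 for complexes II to V, 16 (27) to 39 for ribosomal, 7 (8) to 12 for fast-fibre, 5 (5) to 8 for slow-fibre, 7 (7) to 14 for sarcomere, 4 (7) to 10 for excitation-contraction coupling, 6 (11) to 13 for fatty acid, 10 (15) to 15 for glycolysis, 8 (8) to 14 for heat shock and 2 (7) to 4 for adipocyte genes. Without subA the lowest were 13 (20) to 22 for complex I and 6 (20) to 12 for TCA genes. Without subD they were 1 (15) to 3 for endothelium and 1 (23) to 4 for matrix genes, and without subC 1 (6) to 2 for nerve genes. The places ranged from 86.8% (without subA) to 99.8% for TCA, 81.3% to 98.1% (without subD) for adipocyte and 96.0% (without HuFL) to 99.9% for insulin signalling.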

Other observations

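The gene families and all tests of explanations in this part were chosen after the data had been seen, so a family's place among random lists describes these arrays only. Members are ranked by within-array percentile. Of 33 proteasome subunit genes, 18 were above the floor (median percentile 73.7, place 99.95%), and PSMD11 (5.85 times its floor), PSMB6 (6.99 times) and PSMD8 (6.02 times) were highest-ranked. Of 73 mitochondrial ribosomal protein genes, 35 were above it (median percentile 75.6, place 100%), with MRPL33 (7.37 times) and MRPS18B (6.95 times) highest-ranked. Of 42 translation initiation factor genes, 23 were above it (74.3, place 100%), with EIF3L (16.5 times), EIF3G (13.0 times) and EIF3H (5.45 times) highest-ranked. Small heat shock proteins were taken up because HSPB1, HSPB6 and HSPB7 were among the brightest probe sets, so no place is given. CRYAB (18.6 times), CRYAA (2.76 times), HSPB2 (2.00 times) and HSPB8 (1.81 times) were also above the floor, which made 7 of 8 members, and HSPB3 reached 0.977 times the floor.

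Of 24 interleukin genes, 4 were above the floor, a share higher than in 21.6% of random lists, while the median percentile of 32.4 had a place of 0.40%. The 4 were IL23A (7.43 times the floor), IL32 (8.04 times), IL17D (1.83 times) and IL17B (1.38 times), while IL1B (-427) and IL4 (-272) lay below 0 and IL6 was listed at 0. Of 35 keratin genes, 2 were above the floor, KRT85 (2.37 times) and KRT32 (1.25 times), a share higher than in 1.4% of random lists, while the median percentile had a place of 31.2%. With the HuFL zeros left out, 2 of 31 keratins were above the floor, a share higher than in 3.17% of random lists, and the interleukin median had a place of 1.19%. Of 318 ZNF zinc finger genes, 53 or 16.7% were above the floor against a mean of 23.1% in random lists, a share higher than in 0.17% of them, while the median percentile of 48.0 had a place of 5.33%. ZNF106 (8.78 times), ZNF43 (12.2 times) and ZNF91 (9.49 times) were highest-ranked.

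The 3' actin control was low on HuFL and Hu35K subC, where the 3' over 5' ratio averaged 0.142, against 0.476 on the other 3 arrays. A general loss of the 3' part of transcripts would lower GAPDH too, but the GAPDH ratio was 0.817 on these 2 arrays and 0.741 on the others (SD 0.0666, n = 3), which argues against it. The 3' control of 28S ribosomal RNA over its middle control was also lower within the same arrays, with a mean ratio of -0.176 against 0.349, though its 3' signal was at most 1.52 times the floor on any array. Other probes or features behind some 3' controls may be involved. The ISGF3A 3' control over GAPDH was low on subC (0.0557) but not on HuFL (0.0941, against 0.0877 on subA), so without probe sequences this remains open, and no biological explanation was tested.

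Probe sets of the same gene ranked weakly alike on HuFL and Hu35K. Over 405 probe sets of the same name on HuFL and Hu35K subA, with zeros left out, the Spearman correlation was 0.282 (0.177 to 0.385), but 369 of them were not above the floor on HuFL, and a shared name was not checked against probe sequences. Of the 36 above the floor on HuFL, 17 (47.2%, 30.4 to 64.5) were above it on subA, against 46 of the 369 others (12.5%), and of 9 over 2 floors, 6 were (66.7%, 29.9 to 92.5). Different probes for a gene and signals near the noise floor could each contribute, and these numbers are too few to decide on either. No biological explanation was tested, since both sides measured the same pool.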
